A study of Drosophila melanogaster with 11 samples.

How the data were processed

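RNA was measured in the third antennal segment of w1118 wild-type and mir-284 KO flies at 3 d and 25 d. Per the labels' protocols, total RNA was treated with DNase, polyadenylated RNA was selected, and libraries were made with a kit that marks the strand (NEBNext Ultra Directional) and sequenced on an Illumina NextSeq. The design text describes the replicates as biological. Neither the sex of the flies nor the time of day of dissection is given in the sources used here.

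The deposited table holds raw counts of reads per gene, made by the authors with featureCounts 1.4.5-p1 with strand ignored (setting 0), per the file headers, on dm6 gene models. STAR 2.4.2a, FastQC and dm6 are named in the submitters' processing notes. Because strand was ignored, a gene that overlaps another on the opposite strand cannot be told apart from it; 4161 of the 16727 genes in the table have such exons, and named ones are marked as uncertain. The table has 12 library columns for 11 samples. Columns were matched to samples by genotype, age and replicate number; 1 column, a KO 25 d replicate beyond those the labels list, was not used. The KO 25 d values rest on this match by number. FlyBase IDs were found for 16415 of the 16727 symbols and served only as names. No row without a gene was present.

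All tests ran on the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group, leaving 11867, libraries were scaled by TMM, and the quasi-likelihood test with robust dispersions was run on 1 model of 4 group means over all 11 libraries. The common biological coefficient of variation was 0.431. Contrasts were age in WT, age in KO, KO at 3 d, KO at 25 d, the difference of the age changes between genotypes, and both effects averaged. A positive log2 fold change means higher at 25 d or in KO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p given for a gene comes from this edgeR test unless another tool is named. Fold changes against groups at 0 counts are lower bounds against a limit of 3 counts over the group; these limits and the counting intervals cover counting error only.

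Before the data were examined, 19 gene lists and 9 marker lists of other cell types were fixed: odorant receptors, antennal ionotropic receptors, odorant binding proteins, olfactory signalling, ionotropic glutamate receptors, voltage-gated channels, synaptic vesicle and release, cilium and intraflagellar transport, detoxification enzymes, immune effectors with antimicrobial peptides, heat shock and chaperones, oxidative defence, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, cuticle proteins and tanning, circadian clock, insulin and nutrient signalling, and the microRNA pathway, with markers of neurons, glia, muscle, hemocytes, fat body and females, males, photoreceptors, Johnston's organ, and gustatory and mechanosensory cells. They were tested with camera (limma 3.58.1, inter-gene correlation 0.01), which compares a list with all other genes, adjusted over the 28 lists within a contrast, again with an estimated correlation, and with fry, which tests whether a list's genes move on balance in 1 direction. No list kept its camera call with an estimated correlation in any contrast. Members' p-values were also adjusted over the list alone.

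The rule for named genes was fixed then too. mir-284, w, GluRIIA, GluRIIB and Orco were named whatever their values. For age in WT and KO at each age, the 10 largest increases and 10 largest decreases were named among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' CPM values, 5 and 5 for age in KO and for the averaged KO effect, up to 10 by p for the difference of age changes, and up to 4 called members per list. Genes shown beyond this rule were chosen after their values were seen.

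Simulated counts with the real means and library sizes tested the script on 11867 genes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 45% and 83% of them for age in WT, 18% and 83% for age in KO, 36% and 90% for KO at 3 d, and 22% and 83% for KO at 25 d, with 3, 5, 9 and 5 calls among unchanged genes. By camera, a 1.5-fold change of the 86 ribosomal genes gave adjusted p = 4.79e-26 in the KO 3 d comparison and no other list was called. The single genes to change were drawn from those with a mean of at least 5 CPM. Every gene was simulated independently, and no library was made to stand apart. The simulation therefore does not show how the tests perform with correlated genes or with libraries that stand apart.

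Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom, no filter and a stricter one (at least 10 counts in each library of a group and a mean of 5 CPM), the replicate number as a block, fits of only the groups compared, leaving out genes with opposite-strand overlap, a 1.5-fold threshold and leaving out each library. Voom with library quality weights, 2 and 3 doubted libraries left out, and the roX2 level as a covariate were added after the data were seen. A test of miR-284 seed matches was planned and not run, because no genome sequence was used here.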

Results

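Polyadenylated RNA was sequenced from the third antennal segment, the main olfactory organ of the fly, of Drosophila melanogaster. Wild-type flies of the w1118 strain and flies with a knockout (KO) of the microRNA gene mir-284, outcrossed 7 times to that strain per the labels, were sampled at 3 d and 25 d after eclosion. The study set out to describe which transcripts depend on this microRNA and how they change as flies age. There were 3 libraries in each of the WT 3 d, WT 25 d and KO 3 d groups and 2 in the KO 25 d group. Total counts assigned to genes were 44394382, 38357143 and 34933682 at WT 3 d, 34713579, 37077211 and 24619699 at WT 25 d, 37087180, 36845977 and 29592192 at KO 3 d, and 55485825 and 32844144 at KO 25 d, each in the order of the replicate numbers. All CPM values below are means ± SD of TMM-normalized CPM, with n = 3, or n = 2 for KO 25 d. Coordinates are those of dm6.

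KO 25 d replicate 1 stood apart from the other 10 libraries. Its score on the first principal component, which held 37.7% of the variance, was 163, against -47.6 to 13.3 elsewhere. Its median correlation with the other libraries was 0.896, against 0.939 to 0.964. The odorant binding protein transcript Obp19d took 9.64% of its counts, against 1.57% to 3.60% elsewhere, and 10447 genes were detected in it, against 11801 to 13682. WT 3 d replicate 3 and KO 3 d replicate 3 stood apart on the second component, which held 17.6% of the variance, at 80.1 and 69.4, against -37.2 to 10.7 elsewhere. Ribosomal protein genes took 7.39% and 7.18% of their counts and 10.4% of those of KO 25 d replicate 1, against 4.43% to 5.92% in the other 8 libraries. The spread between the 2 KO 25 d libraries entered the variance shared by all comparisons.

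**Figure D1:**
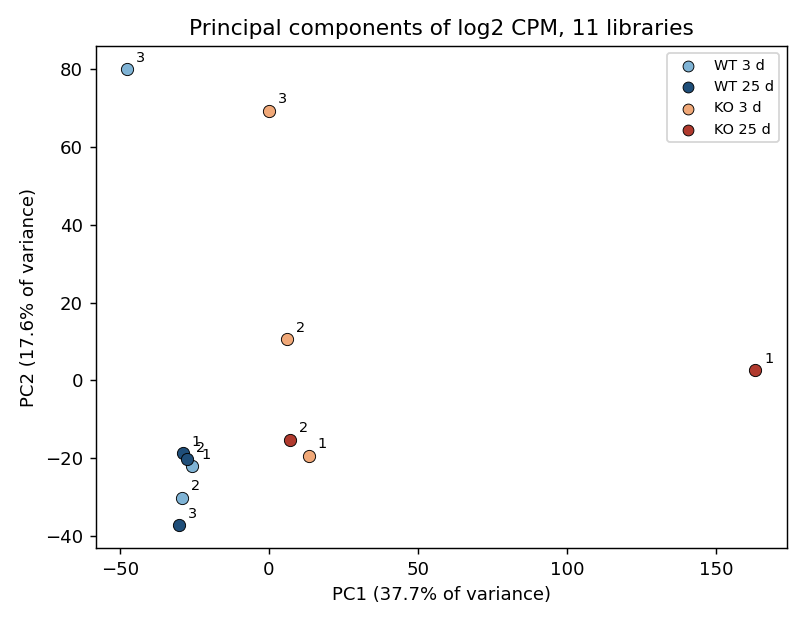
Principal components of log2 CPM, with 1 point per library, colored by group and numbered by replicate; the axes give the share of variance. KO 25 d replicate 1 lies at 163 on the first component and the other 10 libraries between -47.6 and 13.3; WT 3 d replicate 3 and KO 3 d replicate 3 lie at 80.1 and 69.4 on the second and the others between -37.2 and 10.7.

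The targeted gene, mir-284 (3R, 12551515 to 12551614, minus strand), had 0 counts in 11 of 11 libraries, wild type included, which allows at most 0.0677 to 0.110 CPM per library. Poly(A)-selected libraries are not made to hold such a short precursor, so this count checked neither genotype label. The eye pigment transporter gene w (X, 2790599 to 2796466), mutated in the w1118 strain, was at 1.61 ± 0.68 CPM in WT 3 d and 2.82 ± 2.52 in WT 25 d, and 126 ± 24.2 in KO 3 d and 37.7 ± 7.99 in KO 25 d. It was higher in each KO than in every WT library (log2 6.28, SE 0.63, adjusted p = 0.00117 at 3 d and 3.77, SE 0.59, adjusted p = 0.0111 at 25 d). The 25 d call ended without replicate 1 of WT 25 d or KO 25 d. Alleles of w were not compared, so this may not be regulation. GluRIIA (2L, 5555072 to 5558994), a glutamate receptor subunit named in advance as a reported target of miR-284, was at 22.2 ± 3.6 CPM in KO 25 d against 4.21 ± 1.02 in WT 25 d, a log2 fold change of 2.4 (SE 0.32, adjusted p = 0.00589). At 3 d the values were 22.9 ± 2.4 and 10.3 ± 4.35 CPM, and the log2 difference of 1.16 (SE 0.29) did not pass the test (adjusted p = 0.0986). GluRIIB, the other reported target, stayed under 2 CPM in every group mean and passed no test. The olfactory co-receptor gene Orco was at 1934 ± 1070, 2291 ± 131, 2211 ± 550 and 2915 ± 1144 CPM in WT 3 d, WT 25 d, KO 3 d and KO 25 d, and its differences were smaller than the spread between replicates.

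**Figure D2:**
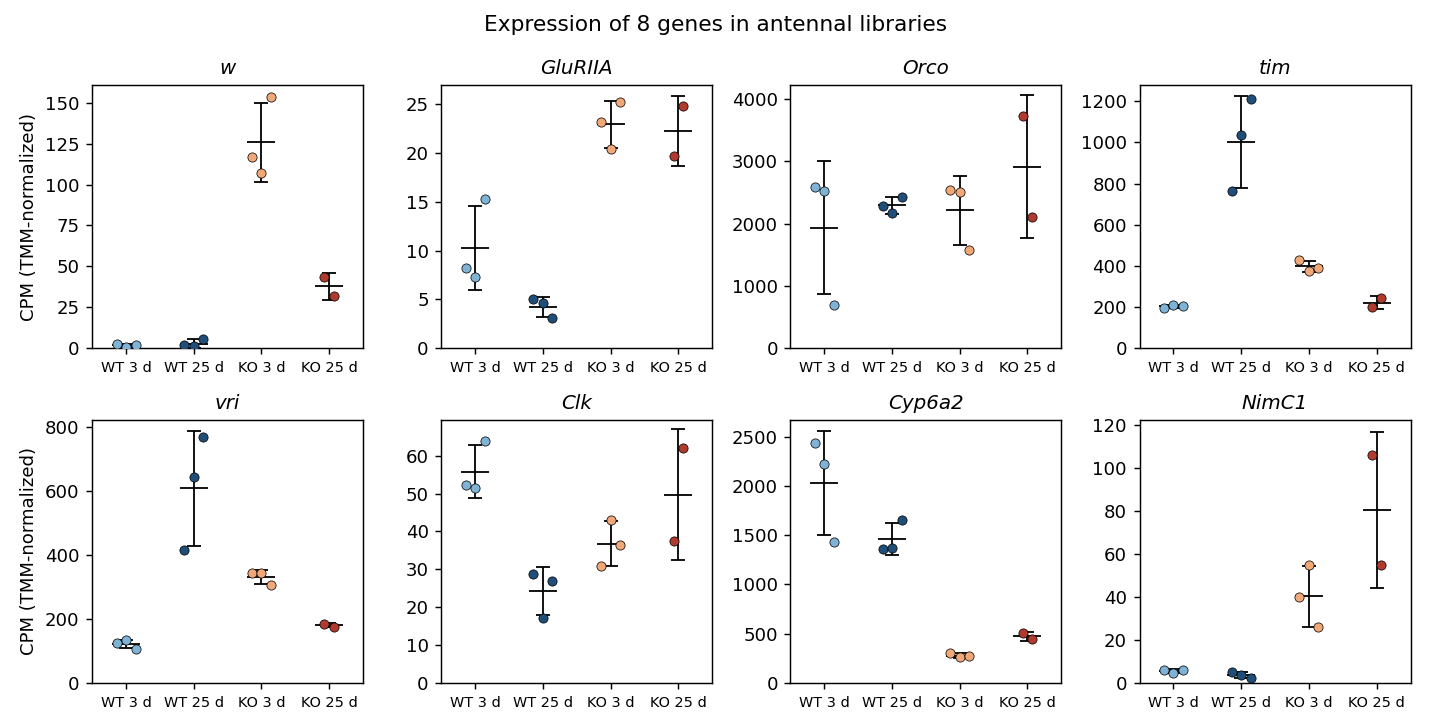
Normalized expression (CPM) of 8 genes, with 1 point per library, horizontal bars at the group mean and error bars of 1 SD (n = 3, or 2 for KO 25 d). tim and vri rose with age in WT and not in KO, Cyp6a2 was lower and NimC1 higher in KO at both ages, and Orco did not differ beyond its spread.

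In wild-type antennae, the circadian clock genes tim and vri rose with age. tim, which encodes a repressor of the clock, went from 203 ± 8.57 to 1003 ± 225 CPM (log2 fold change 2.30, SE 0.19, adjusted p = 0.00266), and vri, which encodes a repressor of Clk, went from 121 ± 13.7 to 610 ± 180 CPM (2.33, SE 0.22, adjusted p = 0.00403). Single genes of muscle and cuticle fell: the log2 fold change was -2.68 for Act79B, an actin of adult muscle (adjusted p = 0.0487), -3.94 for Scp1, a calcium-binding protein (adjusted p = 0.0149), and -2.79 for the cuticle protein gene Cpr49Ae (adjusted p = 0.0487). Further increases were seen for blanks (2.83 ± 1.25 to 26.6 ± 4.34 CPM), the sodium channel gene ppk10 (5.33 ± 0.536 to 29.6 ± 3.77), the maltase gene Mal-A1 and the non-coding RNAs CR42646 and CR44101. Further decreases were seen for Gasp, a chitin-binding protein, for the UDP-glycosyltransferases Ugt86De and Ugt86Da, and for trol, spz3, CG2277 and gb, with log2 fold changes of -0.93 to -2.68. Mal-A1, CG2277 and gb overlap a gene on the other strand and are uncertain, because the counting ignored strand. In total 18 of 11867 genes passed (7 higher and 11 lower). The CPM of the 6 libraries did not overlap between ages for any gene named here, which was a condition for naming them. With upper-quartile scaling the split was 7 higher and 5 lower. Each of the 11 decreases lost its call without WT 3 d replicate 2 (adjusted p of 0.0512 to 0.194 for those named) and without any single WT 25 d library (0.114 to 0.339). All those named except Scp1 and Gasp also lost it without WT 3 d replicate 1 (0.102 to 0.233), and Act79B, Cpr49Ae, trol, spz3 and gb without WT 3 d replicate 3 (0.0501 to 0.102). Of the increases, CR42646, CR44101, ppk10 and Mal-A1 lost theirs without WT 3 d replicate 1 or 2 or any single WT 25 d library (0.0887 to 0.228), ppk10 also without WT 3 d replicate 3 (0.109), and blanks without WT 3 d replicate 2 (0.0534) or WT 25 d replicate 3 (0.0763).

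Of the fixed gene lists, 9 of 28 shifted with age in wild type relative to other genes, by camera. Muscle markers had the lowest adjusted p (4.71e-26, but 0.332 with an estimated correlation). At 25 d 20 of 20 were lower (median log2 -1.58), 1 called over all genes and 17 adjusted over the list alone. Carry-over of tissue in dissection was not tested. Oxidative phosphorylation genes were lower as a list (median -0.36, 70 of 79 members lower, 0 called and 2 adjusted over the list alone, adjusted p = 3.48e-11, and adjusted p = 0.748 with an estimated correlation). Cuticle proteins, immune effectors, detoxification enzymes and photoreceptor markers were also lower, at adjusted p = 0.00104, 0.00491, 0.0156 and 0.0309, and each had adjusted p of at least 0.748 with an estimated correlation. Odorant receptors (median 0.37, 38 of 45 higher, adjusted p = 8.16e-06), antennal ionotropic receptors (0.32, adjusted p = 0.000845) and cilium genes (0.24, adjusted p = 0.000345) were higher as lists, with 0 members called over all genes and 0 adjusted over the list alone, and adjusted p of 0.783, 0.748 and 0.783 with an estimated correlation. Without WT 3 d replicate 3, in which Orco was at 699.97 CPM against 2585 and 2518 CPM in the other WT 3 d libraries, the immune (adjusted p = 0.113) and cilium (0.996) lists turned their direction and the calls of odorant receptors (0.775), antennal ionotropic receptors (0.584), cuticle proteins (0.0669) and photoreceptor markers (0.544) ended. Those of immune effectors (0.108) and photoreceptor markers (0.855) also ended without WT 25 d replicate 1. The other 19 lists did not pass, at adjusted p of 0.0802 to 0.9998. Without KO 25 d replicate 1 or 2 the count of genes became 181 or 184, it was 5 or 2 without WT 3 d replicate 1 or 2, 3, 3 or 2 without WT 25 d replicate 1, 2 or 3, and 8 or 6 without KO 3 d replicate 1 or 2.

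**Figure D3:**
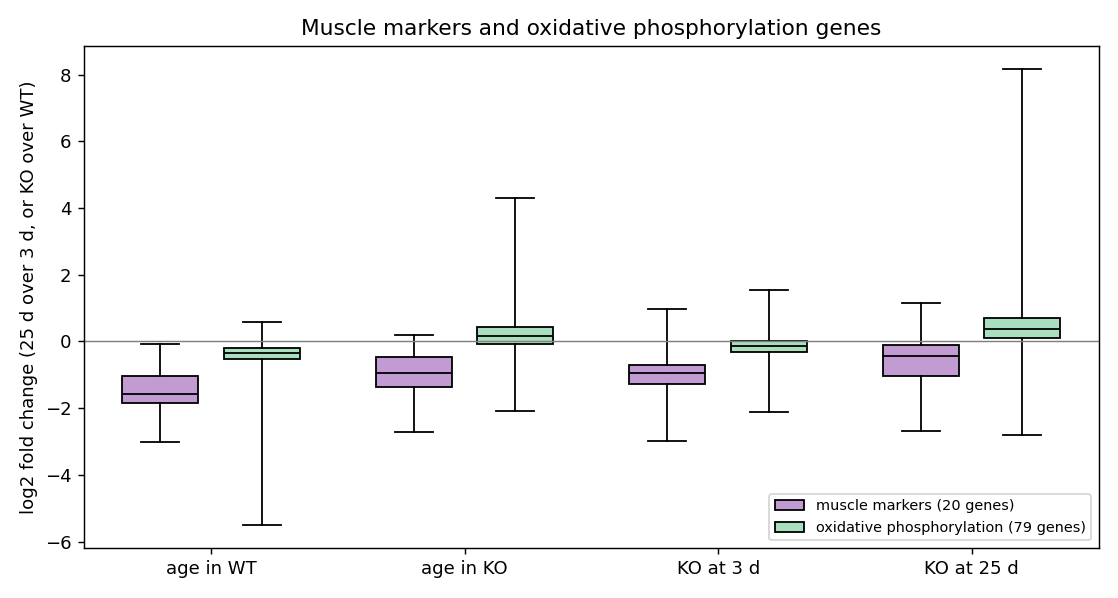
Log2 fold changes of 20 muscle markers and 79 oxidative phosphorylation genes in 4 comparisons (25 d over 3 d, or KO over WT); boxes span the quartiles, lines mark the medians and whiskers reach the lowest and highest gene. Muscle markers had negative medians in each comparison, while the oxidative phosphorylation median was -0.36 for age in WT and 0.38 for KO at 25 d, the latter turning without KO 25 d replicate 1.

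In KO antennae, 5 genes passed for age. CG11893 rose from 10.6 ± 2.43 to 95.7 ± 38 CPM (log2 fold change 3.17, SE 0.27, adjusted p = 0.00282), blanks from 9.32 ± 0.677 to 65.9 ± 33.6 CPM (2.82, adjusted p = 0.0336), and CR45054 and Mal-A1 by 2.80 and 2.55 (adjusted p = 0.0229 and 0.0107). The cytochrome P450 gene Cyp4ac2 fell from 52.4 ± 20.7 to 8.16 ± 0.105 CPM (log2 -2.68, SE 0.35, adjusted p = 0.0361). The calls of Cyp4ac2, blanks and CR45054 ended without any single KO 3 d library (adjusted p of 0.0580 to 0.226) and without KO 25 d replicate 1 (0.281, 0.104 and 0.0853), and that of Mal-A1 without KO 3 d replicate 1 or 2 (0.0599 and 0.0586). The muscle markers were again lower as a list (median -0.95, 19 of 20 members lower, adjusted p = 7.22e-06, and adjusted p = 0.756 with an estimated correlation). Photoreceptor, glia and hemocyte markers and cuticle proteins were lower too, at adjusted p = 4.91e-10, 8.49e-05, 0.00511 and 0.00681, and cytosolic ribosomal proteins were higher (median 0.76, adjusted p = 2.62e-15), all with adjusted p = 0.756 with an estimated correlation. Without KO 25 d replicate 1 the ribosomal list turned (adjusted p = 0.00739, lower) and the calls of glia (0.176) and hemocyte markers (0.230) ended. The calls of muscle (0.344) and photoreceptor markers (0.109) and cuticle proteins (0.437) ended without KO 25 d replicate 2, and that of hemocyte markers (0.0771) without KO 3 d replicate 2. The other 22 lists did not pass, at adjusted p of 0.0721 to 0.985. Leaving out KO 25 d replicate 1 gave 2 calls and leaving out replicate 2 gave 4084, leaving out KO 3 d replicate 1, 2 or 3 gave 1, 1 or 2, leaving out WT 25 d replicate 1, 2 or 3 gave 3, 3 or 2, and a fit of the KO libraries alone gave 0 by edgeR, with 474 genes at an unadjusted p under 0.05. Across the 11867 genes the age changes of WT and KO correlated at r = 0.19 and rho = 0.20, genes not being independent replicates, and r was -0.0356 without WT 3 d replicate 3.

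At 3 d several transcripts were nearly absent in KO, the cause untested. CG14395 (3R, 12662831 to 12673959) was at 23.3 ± 7.15 CPM in WT and had 0 counts in KO, at least 808-fold lower against a limit of 3 counts over the KO group. CG11697 and CG32640 had 0 counts in KO as well, at least 632-fold and at least 261-fold lower. The cytochrome P450 gene Cyp6a17 fell from 118 ± 20.2 to 0.308 ± 0.194 CPM (log2 -8.61, SE 0.60, adjusted p = 9.83e-05). The log2 fold change was -6.73 for CG10462 and -7.85 for CG9589, which overlaps a gene on the other strand. CG32581 rose from 0.252 ± 0.368 to 22.7 ± 11.4 CPM (6.42, adjusted p = 0.00455), the maltase gene Mal-B1 from 9.78 ± 5.45 to 248 ± 74.6 CPM (4.66, adjusted p = 0.00326) and CG13822 from 1.16 ± 0.195 to 15.4 ± 0.684 CPM (3.73, adjusted p = 0.00111). CG9287, CG40472, CG30091, CG31157, PK2-R1 and CG8665 rose by 3.56 to 7.68 on the log2 scale, CG9287 with an overlapping gene on the other strand. CR44922, CG32512, CG10924 and CG34180, the last also overlapping another gene, had log2 fold changes of -3.35 to -4.30. In total 165 genes passed (77 higher and 88 lower). The calls of CG9287 (adjusted p = 0.0600) and CG31157 (0.0565) ended without KO 3 d replicate 1, and those of CG30091 and CG31157 without WT 3 d replicate 1 or 2 (0.0681 to 0.0861). That of PK2-R1 ended without any single library of this age, that of CR44922 without any but WT 3 d replicate 3, that of CG10924 without any but WT 3 d replicate 2, and that of CG8665 without any but WT 3 d replicate 3 or KO 3 d replicate 2 (0.0646 to 0.203).

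Detoxification enzymes held the most calls of any list at 3 d. Of 139 measured, 6 were higher and 11 lower, and adjusted over the list alone 14 were higher and 15 lower. Cyp6a2, a cytochrome P450 with a role in insecticide metabolism, fell from 2029 ± 527 to 278 ± 22 CPM (log2 -2.87, SE 0.23, adjusted p = 0.000198), Cyp4p1 from 572 ± 102 to 116 ± 19.7 CPM (-2.30, adjusted p = 0.000543) and Ugt86Dd from 282 ± 69.2 to 35.4 ± 4.58 CPM (-3.0, adjusted p = 0.000198). Because members moved both ways, the list as a whole did not shift (adjusted p = 0.572). Muscle markers were lower as a list (median -0.95, 19 of 20 members lower, adjusted p = 2.36e-10, and adjusted p = 0.888 with an estimated correlation), with Act88F at -3.0 (adjusted p = 0.00963) and TpnC4 at -2.55 (adjusted p = 0.0379) called, and 6 adjusted over the list alone. NimC1, a phagocytosis receptor of hemocytes, rose from 5.53 ± 0.794 to 40.3 ± 14.4 CPM (2.87, adjusted p = 0.00398). tim and vri were higher in KO at this age, by 0.97 and 1.45 (adjusted p = 0.0326 and 0.00836). Ir41a rose (1.75, adjusted p = 0.0421) and the potassium channel gene Sh fell (-1.10, adjusted p = 0.0421). Cpr73D fell by 1.43 and Cpr51A rose by 1.23 on the log2 scale. The calls of tim, Ir41a, Sh and Cpr51A ended without any single library of this age (adjusted p of 0.0507 to 0.1875), that of Act88F without KO 3 d replicate 1 or 2 (0.0526 and 0.0638), that of TpnC4 without these or WT 3 d replicate 1 or 3 (0.0958 to 0.182), and that of vri without WT 3 d replicate 1 or KO 3 d replicate 1 (0.05015 and 0.0512). The tanning gene b, which encodes an aspartate decarboxylase, fell by 1.87 (adjusted p = 0.0178). This call ended without WT 3 d replicate 1 or 3 or KO 3 d replicate 1 or 2, at adjusted p of up to 0.0972.

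Further lists shifted at 3 d. Proteasome genes (adjusted p = 0.00113), odorant receptors (0.00264), cilium genes (0.00620), fat body and female markers (0.0153) and odorant binding proteins (0.0390) were higher, and cuticle proteins (0.0390) and oxidative phosphorylation genes (0.0455) lower, each with adjusted p = 0.888 with an estimated correlation. Without WT 3 d replicate 3 odorant receptors (adjusted p = 0.774) and cilium genes (0.966) turned and the calls of the proteasome (0.0804) and cuticle proteins (0.484) ended. Calls also ended for cilium genes without KO 3 d replicate 1 (0.0619), for cuticle proteins without KO 3 d replicate 1 or 2 (0.0806 and 0.108), for oxidative phosphorylation without these or WT 3 d replicate 1 (0.0619, 0.184 and 0.183), for fat body and female markers without WT 3 d replicate 1 or 2 (0.105 and 0.0785) and for odorant binding proteins without WT 3 d replicate 1 or KO 3 d replicate 3 (0.154 and 0.383). The labels give no sex: the male-specific RNA roX1 was at 3018 ± 695 CPM in WT and 980 ± 243 CPM in KO at 3 d (log2 -1.62, adjusted p = 0.0476, a gene that overlaps another on the other strand and lost its call without any single library of this age, at adjusted p of 0.0524 to 0.2085), and the male markers were lower as a list (3 of 3, median -1.39, adjusted p = 0.00295, and adjusted p = 0.257 with an estimated correlation). With the level of roX2, another male-specific RNA, as a covariate chosen after the data were seen, 10 genes were called. The other 19 lists did not pass, at adjusted p of 0.0741 to 0.933. Leaving out KO 25 d replicate 1 or 2 gave 591 or 592 calls, leaving out WT 3 d replicate 1 or 2 gave 72 or 71, leaving out WT 25 d replicate 1 or 2 gave 109 or 106, and leaving out KO 3 d replicate 1 or 2 gave 64 or 82.

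At 25 d most of the same transcripts were absent or present in KO. CG11697 and CG32640 had 0 counts in KO (at least 539-fold and at least 200-fold lower), CG14395 had 2 counts, a ratio of 1034 (95% counting interval 286 to 8545), and Cyp6a17 was at 0.141 ± 0.199 against 97.9 ± 8.34 CPM (log2 -9.46, adjusted p = 0.00094). The log2 fold change was -3.87 for Cyp4ac2 (adjusted p = 0.00116), -3.50 for Cyp4d8 (adjusted p = 0.00138) and -1.92 for Ugt86Dd (adjusted p = 0.00677), and it lay between -8.35 and -3.89 for CG10462, CG9589, CR44922, CG16886 and CG9928. Arc1, a gene that encodes a retrovirus-like capsid protein, rose from 80.6 ± 12.4 to 2622 ± 1770 CPM (5.02, SE 0.50, adjusted p = 0.00116), NimC1 from 3.59 ± 1.42 to 80.6 ± 36.3 CPM (4.48, SE 0.42, adjusted p = 0.00116) and CG32581 by 8.57 (adjusted p = 0.00388). The antimicrobial peptide genes AttA, Dro and Listericin were higher by 6.91, 6.46 and 4.98, and CG10814, at 0 counts in WT 25 d, was at least 1563-fold higher, but these calls ended without KO 25 d replicate 1. CG30091, CG31157 and CR43264 rose by 4.84 to 5.29. The calls of AttA, Dro, Listericin, CG10814, CR43264, CR44922 and CG16886 also ended without any single WT 25 d library (adjusted p of 0.05625 to 0.169), that of CR43264 without KO 25 d replicate 1 (0.0676), that of CG30091 without WT 25 d replicate 3 (0.0527), and that of CG9928 without any single library of this age (0.0504 to 0.400). tim and vri were lower in KO, at log2 -2.18 and -1.76 (adjusted p = 0.00126 and 0.00677). In total 206 genes passed (117 higher and 89 lower).

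Among the lists at 25 d, detoxification enzymes again held the most calls, with 11 higher and 8 lower of 139, and 26 and 20 adjusted over the list alone; the list itself did not shift (adjusted p = 0.601). The peroxiredoxin gene Prx2540-2 and GstD1 of the oxidative defence list rose by 2.4 and 1.73 (list adjusted p = 0.0254), and of the cuticle list Cpr64Ac and Cpr51A rose by 2.72 and 1.61 while Cht2, which overlaps another gene, fell by 0.99. The tanning gene b fell by 1.84 (adjusted p = 0.03555). This call ended without KO 25 d replicate 1 or any WT 25 d library, at adjusted p of up to 0.132. Act88F fell by 2.69 (adjusted p = 0.0350), and Obp58d rose by 2.90 (adjusted p = 0.0432). The calls of GstD1, Cpr51A, Cht2 and Act88F ended without any single WT 25 d library (0.0740 to 0.163), those of GstD1 and Act88F without KO 25 d replicate 1 (0.204 and 0.306), and that of Obp58d without WT 25 d replicate 1 or 3 or KO 25 d replicate 1 (0.161, 0.183 and 0.275). Immune effectors were higher as a list (median 1.12, 42 of 54 members higher, 2 called, adjusted p = 0.00024), as were ribosomal proteins (0.86, adjusted p = 3.60e-12), the proteasome and oxidative phosphorylation (both adjusted p = 0.00492), and photoreceptor and glia markers were lower (adjusted p = 0.000828 and 0.00919). All 7 lists had adjusted p = 0.931 with an estimated correlation. Without KO 25 d replicate 1 the ribosomal list (adjusted p = 0.542), oxidative phosphorylation (adjusted p = 7.65e-05, lower) and the proteasome (adjusted p = 0.933) turned, and the calls of immune effectors (adjusted p = 0.0769), glia markers (0.533) and oxidative defence (0.840) ended. That of photoreceptor markers ended without KO 25 d replicate 2 (0.481). The other 21 lists did not pass, at adjusted p of 0.0722 to 0.910. There were 90, 76 or 68 calls without WT 25 d replicate 1, 2 or 3, and 14 with the roX2 covariate, which has the limit given for 3 d.

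The KO differences at 3 d and 25 d were alike in direction. Of the 165 genes called at 3 d, 157 had the same sign at 25 d, 41 were called higher at both ages (0.76 by chance for independent lists), 54 lower at both ages (0.66 by chance), and 2 in opposite directions. Over all 11867 genes the log2 fold changes correlated at r = 0.40 and rho = 0.43, genes not being independent replicates; these comparisons share no library. Averaged over ages, 631 genes passed (345 higher and 286 lower).

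Among called genes with a mean of at least 5 CPM and no overlap of WT and KO values at either age, the largest increases averaged over ages were those of CG9287, CG32581 (log2 7.49, adjusted p = 0.000168), w (5.02, adjusted p = 0.000149), CG30091 (4.8, adjusted p = 0.000499) and Dro (4.70, adjusted p = 0.00918). CG9287, which overlaps a gene on the other strand, had 6 counts in WT 3 d and 0 in WT 25 d and was at 10.5 ± 4.23 and 2.66 ± 0.271 CPM in KO 3 d and KO 25 d (adjusted p = 0.0012). The largest decreases were those of CG11697 and CG32640, with 0 counts in each KO library, CG14395, with 2 counts over the KO libraries, Cyp6a17 (-9.04) and CG10462 (-7.54). Their adjusted p was 2.43e-05 to 0.000105. GluRIIA rose by 1.78 on the log2 scale (SE 0.22, adjusted p = 0.00119), and GluRIA, another glutamate receptor subunit, was lower, at 1.03 ± 1.54 and 0.183 ± 0.259 CPM in KO against 11.6 ± 2.26 and 11.6 ± 3.5 in WT (-4.75, adjusted p = 0.0293). Of the chemosensory lists, the odorant receptor gene Or42a rose by 2.68 (adjusted p = 0.0458), Ir41a by 1.37, Obp49a by 1.43 and Obp58d by 2.23, and Ir31a fell by 0.79. Obp56b, with 1 count over the WT libraries, was at 1.13 ± 0.731 and 2.35 ± 3.13 CPM in KO (adjusted p = 0.0101). Obp57e was at 0.724 ± 0.41 and 1.66 ± 1.87 CPM against 0.0408 ± 0.0388 and 0.0343 ± 0.0387 CPM in WT (adjusted p = 0.0209). AttA rose by 4.89. PGRP-LB, a negative regulator of the immune response, fell by 0.78 (adjusted p = 0.00814). Prx2540-2, GstD1, the thioredoxin gene Trx-2 and the chaperone gene Hsc70-2 rose by 1.89, 1.36, 0.57 and 0.72. AttA and Prx2540-2 have near-identical copies in the genome and are uncertain. Cyp4d8, Ugt86Dd and Cyp6a2 had log2 fold changes of -3.02, -2.46 and -2.25 (each adjusted p = 0.000105). In the cuticle list Cpr64Ac and Cpr51A rose by 1.94 and 1.42, and b and Cpr73D fell by 1.85 and 0.97. The vesicular monoamine transporter gene Vmat, which overlaps another gene, fell by 0.60, the neuropeptide gene Dh44 by 3.74 and tim by 0.61. CG15666 of the cilium list rose by 0.98. Of the marker lists, Act88F, TpnC4 and Act79B of muscle fell by 2.85, 2.16 and 1.66, inaE of photoreceptors by 0.65 and roX2 by 1.26. NimC1 of hemocytes (3.67), Lsp1beta (4.21) and tsl (1.46) of fat body and females and Dhc93AB of Johnston's organ (0.94) rose. The calls of Dro (adjusted p = 0.0631) and Act79B (0.0679) ended without KO 25 d replicate 1. Those of Or42a, Ir31a, Obp57e, GluRIA, Vmat, CG15666, Hsc70-2, Trx-2, tim, Dh44, Lsp1beta, tsl, inaE and Dhc93AB ended without WT 25 d replicate 3 (0.0548 to 0.120). Each of these 14 also ended without at least 4 of the other libraries, KO 25 d replicate 2 not among them, at adjusted p of up to 0.157. With the roX2 covariate the calls of CG11697, CG32640, CG14395, Cyp6a17 and CG10462 held. Those of the other genes named here ended, roX2 itself aside.

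Of the detoxification enzymes 22 were higher and 17 lower, and 36 and 21 adjusted over the list alone. By camera 10 of 28 lists shifted: ribosomal proteins (adjusted p = 8.07e-06), the proteasome (0.000435), immune effectors (0.00555), oxidative defence (0.0394) and odorant binding proteins (0.0416) were higher, and muscle (3.50e-05), male (0.0253), photoreceptor (0.0357) and glia markers (0.0360) and cuticle proteins (0.0394) lower. All had adjusted p = 0.941 with an estimated correlation, except the male markers at adjusted p = 0.673 with an estimated correlation, and the other 18 lists had adjusted p of 0.0506 to 0.864. Leaving out KO 25 d replicate 1, the calls of ribosomal proteins (0.965), the proteasome, immune effectors and cuticle proteins (each 0.0950), oxidative defence (0.439), odorant binding proteins (0.460) and glia markers (0.364) ended, and without replicate 2 those of muscle (0.0817), male (0.190) and photoreceptor markers (0.480) and cuticle proteins (0.284). With the roX2 covariate 12 genes were called. Without WT 3 d replicate 1 or 2 the count was 370 or 366, without WT 25 d replicate 1, 2 or 3 it was 391, 363 or 374, without KO 3 d replicate 1 or 2 it was 382 or 415, and without KO 25 d replicate 2 it was 4950.

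Averaged over genotypes, 51 genes changed with age (18 higher and 33 lower; 21 higher and 25 lower with upper-quartile scaling). They included Act79B (log2 -2.70, adjusted p = 0.0118), the cuticle protein genes Cpr47Ef (-3.20, adjusted p = 0.0118) and Cpr49Ae (-2.48, adjusted p = 0.0131), and nrv2, a sodium pump subunit of glia (-0.81, adjusted p = 0.0211). Obp56a rose by 2.61 (adjusted p = 0.0304), and GstS1 and Cyp4ac2 fell by 0.66 and 1.56. The glutathione transferase gene GstE13 and, of the oxidative phosphorylation list, CG5548, both overlapping another gene, fell by 1.09 and 0.64 (adjusted p = 0.0224 and 0.0448). Each of these 9 calls ended without WT 25 d replicate 3 (adjusted p = 0.0563 to 0.114). All but that of Cpr49Ae also ended without WT 25 d replicate 1 or 2 (0.0520 to 0.1365). Those of nrv2, Obp56a, GstS1, Cyp4ac2, GstE13 and CG5548 also ended without WT 3 d replicate 1 or 2 or KO 3 d replicate 1 (0.0506 to 0.1295). Those of Obp56a, GstS1 and CG5548 ended without KO 3 d replicate 2 or 3 (0.0534 to 0.0832), those of Cpr47Ef, Cyp4ac2 and CG5548 without KO 25 d replicate 1 (0.0514 to 0.0570), and that of CG5548 without WT 3 d replicate 3 (0.0587). By camera 9 of 28 lists shifted: muscle (adjusted p = 5.54e-19), photoreceptor (7.39e-09), glia (0.00034) and hemocyte markers (0.00284), cuticle proteins (0.000332) and oxidative phosphorylation (0.00937) were lower, and ribosomal proteins (7.90e-07), cilium genes (0.00284) and odorant receptors (0.0275) higher. These had adjusted p of 0.644 to 0.860 with an estimated correlation, and the other 19 lists had adjusted p of 0.0879 to 0.960. Ribosomal proteins turned (0.0222) without KO 25 d replicate 1, and the calls of glia (0.0920) and hemocyte markers (0.100) ended. Without replicate 2 oxidative phosphorylation turned (0.0913), and the calls of photoreceptor markers (0.0572), cuticle proteins (0.133), cilium genes (0.0738) and odorant receptors (0.504) ended. Cilium genes (0.368) and odorant receptors (0.932) also lost theirs without WT 3 d replicate 3. The count was 10 or 17 without WT 3 d replicate 1 or 2, 9, 7 or 6 without WT 25 d replicate 1, 2 or 3, 14, 28 or 33 without KO 3 d replicate 1, 2 or 3, and 88 or 3466 without KO 25 d replicate 1 or 2.

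The change with age differed between genotypes for 3 genes. tim rose by 2.30 in WT, and the difference of the age changes, KO minus WT, was -3.15 (SE 0.29, adjusted p = 0.00648). vri gave -3.21 (SE 0.33, adjusted p = 0.00903). CG11893, at 11.9 ± 1.23 and 13.9 ± 1.82 CPM in WT 3 d and 25 d, rose more in KO (difference 2.96, SE 0.36, adjusted p = 0.0257). The call of tim ended without WT 3 d replicate 1, that of vri without WT 3 d replicate 1, WT 25 d replicate 2, or KO 3 d replicate 1 or 2, and that of CG11893 without any of the 9 libraries outside KO 25 d. The count was 0 without WT 3 d replicate 1 (edgeR, with 554 genes at an unadjusted p under 0.05; on all 11 libraries DESeq2 called 43 and limma voom 2), 1 without WT 25 d replicate 2 or KO 3 d replicate 1 or 2, 6 without KO 25 d replicate 1 and 2987 without replicate 2. Among the lists, 10 of 28 shifted in this test, and each of these calls ended without KO 25 d replicate 1 or without replicate 2. Each had adjusted p = 0.734 with an estimated correlation, and the other 18 had adjusted p of 0.0771 to 0.973.

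Genes near the targeted locus were called more often. Within 2 Mb of mir-284, 37 of 428 tested genes (8.64%) were called for KO averaged over ages, against 594 of 11439 elsewhere (5.19%; Fisher's exact test, 2-sided, p = 0.003996). By the same exact test, 19 were called at 25 d (4.44%, against 1.63%, p = 0.0001661) and 11 at 3 d (2.57%, against 1.35%, p = 0.05283). At 25 d the exact p was 0.05678 without WT 25 d replicate 2 and 0.2069 without KO 25 d replicate 2, and averaged over ages it was 0.2832 without KO 25 d replicate 2. Of the genes named for KO, CG14395, CG31157, Ugt86Dd, GstD1, PGRP-LB, Hsc70-2 and PK2-R1 lie on 3R within this window, as do Ugt86Da and Ugt86De, named for age in WT.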

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

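The tests of the time of day and of KO 25 d replicate 1 as sole source were chosen only after the result was seen. The age change differed between genotypes for tim, vri and CG11893 in the edgeR test of the difference, KO minus WT. For tim the log2 difference was -3.15 (adjusted p = 0.00648): tim went from 194 to 210 CPM in WT 3 d libraries to 764 to 1209 CPM in WT 25 d, and from 374 to 429 CPM in KO 3 d to 198 and 245 CPM in KO 25 d. For vri it was -3.21 (adjusted p = 0.00903), and for CG11893, which was at 68.9 and 123 CPM in KO 25 d and at 7.98 to 15.95 CPM in the other libraries, 2.96 (adjusted p = 0.0257).

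A difference in the time of day of dissection may account for the tim and vri result, since both cycle daily. It would move per with tim and Clk against it: the difference was -1.93 for per (SE 0.33) and 1.64 for Clk (SE 0.36), while Pdp1 (0.28, SE 0.37), cwo (-0.18, SE 0.26) and cry (0.49, SE 0.37) were less clear. No collection time is given in the sources used here, so time of day and an effect of genotype on the clock, which was not tested, cannot be told apart. KO 25 d replicate 1 was argued against as the sole source: without it the difference for tim was -3.0 (SE 0.32, adjusted p = 0.0275).

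By camera, 10 lists differed in their age change. The difference was higher in KO for ribosomal proteins (adjusted p = 1.34e-14, median log2 0.83, 84 of 86 members positive), oxidative phosphorylation (2.20e-08, 0.55, 71 of 79), immune effectors (0.000125, 1.23, 40 of 54), muscle markers (0.00484, 0.48, 17 of 20) and voltage-gated channels (0.0198, 0.16, 19 of 26). It was lower for photoreceptor markers (1.07e-05, -1.54, 0 of 17 positive), odorant receptors (0.00188, -0.45, 9 of 45), antennal ionotropic receptors (0.0186, -0.42, 3 of 19), glia markers (0.0196, -0.32, 2 of 15) and the circadian clock (0.0305, median 0.05). Each had adjusted p = 0.734 with an estimated correlation. In the circadian clock 2 members were called lower, and 1 was higher and 3 lower adjusted over the list alone; in the other 9 lists edgeR called 0 members, 0 adjusted over the list alone, as did DESeq2 and limma voom, and 0 to 8 members per list had an unadjusted p under 0.05. Without KO 25 d replicate 1, ribosomal proteins (adjusted p = 0.159) and oxidative phosphorylation (0.128) turned, and the calls of immune effectors (0.326), muscle markers (0.111), antennal ionotropic receptors (0.335), odorant receptors (0.0514), glia markers (0.916) and the circadian clock (0.232) ended. The calls of the remaining lists, photoreceptor markers (0.346) and voltage-gated channels (0.758), ended without KO 25 d replicate 2, so each of the 10 calls ended without 1 or the other of these 2 libraries.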

How the results depend on the processing

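Voom with library quality weights, the fits without 2 libraries (KO 25 d replicate 1 and WT 3 d replicate 3) or 3 (KO 3 d replicate 3 as well), the list tests without those 3, and the roX2 covariate were chosen only after the data were seen. Counts without the doubted libraries had been seen before that alternative was written down, and they do not replace the counts of all 11 libraries. With 3 libraries left out, or 1 KO 25 d library, the lone KO 25 d library was assumed to vary like the other groups. Under all alternatives together, values of named genes kept direction and side of the threshold in 2831 cases, lost the call in 696, gained one in 15 and turned in 38; called lists kept it in 466, lost it in 245 and turned in 21; counts, agreement and locus results stayed in 174, moved in 102, gained a call in 6, lost it in 3 and turned in 1. Where a result changed, the cause was not tested, except that leaving out genes with opposite-strand overlap tested fewer genes. Depth was 24619699 to 55485825 counts per library; the 2 KO 25 d libraries limited the precision at that age. The planned test of miR-284 seed matches was not run, because no genome sequence was used here.

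Counts stayed within 1.5 times for all 7 comparisons under RLE scaling, upper-quartile scaling, no filter and a 1.5-fold threshold. In the order age in WT, age in KO, KO at 3 d, KO at 25 d, difference of age changes, KO averaged and age averaged, edgeR called 18, 5, 165, 206, 3, 631 and 51 genes and DESeq2 called 295, 280, 564, 1078, 43, 1558 and 630. Quality weights gave 1990, 1, 2382, 25, 2, 373 and 19, the fit without 2 libraries 239, 6, 756, 273, 11, 945 and 288, and that without 3 libraries 1099, 209, 1509, 888, 87, 1975 and 1091. The roX2 covariate gave 12, 5, 10, 14, 2, 12 and 51. Fits of only the groups compared gave 121, 0, 245 and 20 for the first 4. The 0 came from edgeR with 474 of 10927 genes at an unadjusted p under 0.05, fewer than chance alone would give. Limma voom called 30 for age averaged, the stricter filter 5 for the difference of age changes, and 10 passed for age in WT without opposite-strand overlap. Leaving out single libraries gave 2 (WT 3 d replicate 2) to 18 among the WT libraries for age in WT, with 181 and 184 without KO 25 d replicate 1 and 2, 1 (KO 3 d replicate 1) to 4084 for age in KO, 64 (KO 3 d replicate 1) to 157 among the 3 d libraries for KO at 3 d, with 591 and 592 without KO 25 d replicate 1 and 2, 68 (WT 25 d replicate 3) to 5090 for KO at 25 d, 0 (WT 3 d replicate 1) to 2987 for the difference of age changes, 363 (WT 25 d replicate 2) to 4950 for KO averaged and 6 (WT 25 d replicate 3) to 3466 for age averaged. The highest counts of the last 4 and of age in KO came without KO 25 d replicate 2. The 0 came from edgeR with 554 genes at an unadjusted p under 0.05, where DESeq2 on 11 libraries called 43 and limma voom 2.

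The libraries share replicate numbers across groups. Correlations of same-numbered libraries' deviations from the group means ran from -0.118 to 0.465 over all pairs of groups. At 3 d, WT and KO replicates 1 (0.408) and 3 (0.465) deviated together and replicates 2 did not (0.0254), and WT replicate 2 correlated best with KO replicate 1 (0.504). Because not every pair was over 0.1, the numbers were not taken to pair the samples. With the replicate number as a block, 12, 2, 117, 145, 2, 490 and 20 genes were called, and the agreement of age changes was r = 0.117. Adjusted p of lists that lost their call under the block was 0.0525 for oxidative phosphorylation (KO at 3 d), 0.0617 for oxidative defence (KO at 25 d), 0.0823 for voltage-gated channels (the difference of age changes), 0.0720 for cuticle proteins, 0.0568 for male markers, 0.0622 for odorant binding proteins, 0.0720 for oxidative defence and 0.0648 for photoreceptor markers (KO averaged over ages) and 0.156 for odorant receptors (age averaged over genotypes), and 5 lists were called for KO averaged over ages. The block turned GluRIIA for age in KO (log2 0.0418) and Orco for the difference of age changes (-0.275).

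The numbers of lists called were 9, 6, 9, 7, 10, 10 and 9, in the order above. With an estimated correlation 0 were called in each comparison, and by fry 0, 0, 1, 0, 0, 1 and 0, the male markers in both cases (adjusted p = 0.0287 and 0.0200). KO averaged over ages gave 3 without the 3 libraries, 12 without WT 3 d replicate 2, 5 without KO 3 d replicate 1 and 4 without KO 25 d replicate 1. Without KO 25 d replicate 1 there were 12 for age in KO (5 without KO 3 d replicate 2), 3 for KO at 25 d (9 without WT 25 d replicate 3) and 6 for the difference of age changes (6 also without replicate 2, and 12 without WT 25 d replicate 3). Median, mean and test differed in sign for 5, 4, 4, 5, 3, 4 and 4 lists, of which 1 was called, the circadian clock in the difference of age changes (median 0.05, mean -0.31, lower by camera).

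For age in WT, the lists called were antennal ionotropic receptors, immune effectors, cilium genes, cuticle proteins, detoxification enzymes, muscle markers, odorant receptors, oxidative phosphorylation and photoreceptor markers. For age in WT, adjusted p with an estimated correlation was 0.748, 0.786, 0.783, 0.748, 0.748, 0.332, 0.783, 0.748 and 0.783, in that order. By fry, age in WT gave 0.650, 0.659, 0.650, 0.610, 0.610, 0.329, 0.650, 0.610 and 0.659, in that order. Age in WT without the 3 libraries gave 0.623 for antennal ionotropic receptors, 0.287 (opposite direction) for immune effectors, 0.839 (opposite direction) for cilium genes, 0.445 for cuticle proteins, 0.623 for odorant receptors and 0.623 for photoreceptor markers. Single omissions for age in WT gave a lowest adjusted p of 2.44e-06 for antennal ionotropic receptors, 3.72e-07 for immune effectors, 7.94e-08 for cilium genes, 3.76e-05 for cuticle proteins, 1.55e-11 for odorant receptors and 3.86e-05 for photoreceptor markers. Immune effectors (0.108) and photoreceptor markers (0.855) changed without WT 25 d replicate 1. Antennal ionotropic receptors (0.584), immune effectors (0.113, opposite direction), cilium genes (0.996, opposite direction), cuticle proteins (0.0669), odorant receptors (0.775) and photoreceptor markers (0.544) changed without WT 3 d replicate 3.

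For age in KO, the lists called were cuticle proteins, ribosomal proteins, glia markers, hemocyte markers, muscle markers and photoreceptor markers. For age in KO, adjusted p with an estimated correlation was 0.756 for each. By fry, age in KO gave 0.407, 0.636, 0.407, 0.409, 0.409 and 0.407, in that order. Age in KO without the 3 libraries gave 0.0916 for cuticle proteins, 0.676 for ribosomal proteins, 0.0747 for glia markers and 0.131 for hemocyte markers. Single omissions for age in KO gave a lowest adjusted p of 0.000607 for cuticle proteins, 1.15e-27 for ribosomal proteins, 0.000130 for glia markers, 0.000811 for hemocyte markers, 1.51e-09 for muscle markers and 1.05e-17 for photoreceptor markers. Ribosomal proteins (0.00739, opposite direction), glia markers (0.176) and hemocyte markers (0.230) changed without KO 25 d replicate 1. Cuticle proteins (0.437), muscle markers (0.344) and photoreceptor markers (0.109) changed without KO 25 d replicate 2. Hemocyte markers (0.0771) changed without KO 3 d replicate 2.

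For KO at 3 d, the lists called were cilium genes, cuticle proteins, fat body and female markers, male markers, muscle markers, odorant binding proteins, odorant receptors, oxidative phosphorylation and proteasome. For KO at 3 d, adjusted p with an estimated correlation was 0.888, 0.888, 0.888, 0.257, 0.888, 0.888, 0.888, 0.888 and 0.888, in that order. By fry, KO at 3 d gave 0.683 for cilium genes, 0.569 for cuticle proteins, 0.569 for fat body and female markers, 0.414 for muscle markers, 0.683 for odorant binding proteins, 0.715 for odorant receptors, 0.715 for oxidative phosphorylation and 0.569 for proteasome. KO at 3 d without the 3 libraries gave 0.208 for cilium genes, 0.270 for cuticle proteins, 0.149 for male markers, 0.149 for odorant binding proteins and 0.106 for odorant receptors. Single omissions for KO at 3 d gave a lowest adjusted p of 7.90e-06 for cilium genes, 0.00748 for cuticle proteins, 8.60e-07 for fat body and female markers, 0.00389 for odorant binding proteins, 9.69e-08 for odorant receptors, 0.0204 for oxidative phosphorylation and 1.20e-05 for proteasome. Cilium genes (0.0619), cuticle proteins (0.0806) and oxidative phosphorylation (0.0619) changed without KO 3 d replicate 1. Cuticle proteins (0.108) and oxidative phosphorylation (0.184) changed without KO 3 d replicate 2. Odorant binding proteins (0.383) changed without KO 3 d replicate 3. Fat body and female markers (0.105), odorant binding proteins (0.154) and oxidative phosphorylation (0.183) changed without WT 3 d replicate 1. Fat body and female markers (0.0785) changed without WT 3 d replicate 2. Cilium genes (0.966, opposite direction), cuticle proteins (0.484), odorant receptors (0.774, opposite direction) and proteasome (0.0804) changed without WT 3 d replicate 3.

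For KO at 25 d, the lists called were immune effectors, ribosomal proteins, glia markers, oxidative defence, oxidative phosphorylation, photoreceptor markers and proteasome. For KO at 25 d, adjusted p with an estimated correlation was 0.931 for each. By fry, KO at 25 d gave 0.503, 0.484, 0.315, 0.384, 0.583, 0.384 and 0.484, in that order. KO at 25 d without the 3 libraries gave 0.0897 for immune effectors, 0.508 (opposite direction) for ribosomal proteins, 0.209 for glia markers, 0.985 for oxidative defence, 8.65e-05 (opposite direction) for oxidative phosphorylation and 0.994 for proteasome. Single omissions for KO at 25 d gave a lowest adjusted p of 1.56e-06 for immune effectors, 3.21e-25 for ribosomal proteins, 0.00459 for glia markers, 0.00246 for oxidative defence, 5.84e-12 for oxidative phosphorylation, 4.41e-08 for photoreceptor markers and 0.000368 for proteasome. Immune effectors (0.0769), ribosomal proteins (0.542, opposite direction), glia markers (0.533), oxidative defence (0.840), oxidative phosphorylation (7.65e-05, opposite direction) and proteasome (0.933, opposite direction) changed without KO 25 d replicate 1. Photoreceptor markers (0.481) changed without KO 25 d replicate 2. The highest adjusted p for oxidative phosphorylation was 0.0127, without WT 25 d replicate 3, in the same direction.

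For the difference of age changes, the lists called were antennal ionotropic receptors, immune effectors, circadian clock, ribosomal proteins, glia markers, muscle markers, odorant receptors, oxidative phosphorylation, photoreceptor markers and voltage-gated channels. For the difference of age changes, adjusted p with an estimated correlation was 0.734 for each. By fry, the difference of age changes gave 0.707 for each. The difference of age changes without the 3 libraries gave 0.746 (opposite direction) for antennal ionotropic receptors, 0.186 (opposite direction) for immune effectors, 0.325 for circadian clock, 0.0170 (opposite direction) for ribosomal proteins, 0.890 for glia markers, 0.161 for odorant receptors and 0.545 (opposite direction) for oxidative phosphorylation. Single omissions for the difference of age changes gave a lowest adjusted p of 0.000426 for antennal ionotropic receptors, 1.57e-08 for immune effectors, 0.00115 for circadian clock, 4.05e-25 for ribosomal proteins, 0.0112 for glia markers, 2.53e-09 for muscle markers, 4.29e-07 for odorant receptors, 5.42e-18 for oxidative phosphorylation, 4.64e-12 for photoreceptor markers and 9.12e-05 for voltage-gated channels. Antennal ionotropic receptors (0.335), immune effectors (0.326), circadian clock (0.232), ribosomal proteins (0.159, opposite direction), glia markers (0.916), muscle markers (0.111), odorant receptors (0.0514) and oxidative phosphorylation (0.128, opposite direction) changed without KO 25 d replicate 1. Antennal ionotropic receptors (0.0666), circadian clock (0.647), muscle markers (0.0870), odorant receptors (0.105), photoreceptor markers (0.346) and voltage-gated channels (0.758) changed without KO 25 d replicate 2. Antennal ionotropic receptors (0.0728), circadian clock (0.0703) and muscle markers (0.0798) changed without KO 3 d replicate 1. Circadian clock (0.143) and muscle markers (0.0784) changed without KO 3 d replicate 2. Voltage-gated channels (0.226) changed without KO 3 d replicate 3. Circadian clock (0.0613) changed without WT 3 d replicate 1. Voltage-gated channels (0.115) changed without WT 3 d replicate 2. Antennal ionotropic receptors (0.528), immune effectors (0.528), circadian clock (0.139), muscle markers (0.187) and odorant receptors (0.743) changed without WT 3 d replicate 3.

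For KO averaged over ages, the lists called were immune effectors, cuticle proteins, ribosomal proteins, glia markers, male markers, muscle markers, odorant binding proteins, oxidative defence, photoreceptor markers and proteasome. For KO averaged over ages, adjusted p with an estimated correlation was 0.941, 0.941, 0.941, 0.941, 0.673, 0.941, 0.941, 0.941, 0.941 and 0.941, in that order. By fry, KO averaged over ages gave 0.474 for immune effectors, 0.217 for cuticle proteins, 0.478 for ribosomal proteins, 0.217 for glia markers, 0.217 for muscle markers, 0.474 for odorant binding proteins, 0.272 for oxidative defence, 0.474 for photoreceptor markers and 0.217 for proteasome. KO averaged over ages without the 3 libraries gave 0.204 for cuticle proteins, 0.836 for ribosomal proteins, 0.204 for glia markers, 0.204 for male markers, 0.964 for odorant binding proteins, 0.649 for oxidative defence, 0.172 for photoreceptor markers and 0.211 for proteasome. Single omissions for KO averaged over ages gave a lowest adjusted p of 3.71e-08 for immune effectors, 0.0163 for cuticle proteins, 2.07e-17 for ribosomal proteins, 0.00609 for glia markers, 0.00284 for male markers, 9.18e-11 for muscle markers, 0.00562 for odorant binding proteins, 0.00513 for oxidative defence, 0.000479 for photoreceptor markers and 1.52e-05 for proteasome. Immune effectors (0.0950), cuticle proteins (0.0950), ribosomal proteins (0.965), glia markers (0.364), odorant binding proteins (0.460), oxidative defence (0.439) and proteasome (0.0950) changed without KO 25 d replicate 1. Cuticle proteins (0.284), male markers (0.190), muscle markers (0.0817) and photoreceptor markers (0.480) changed without KO 25 d replicate 2. Cuticle proteins (0.0577), glia markers (0.0516), odorant binding proteins (0.0516), oxidative defence (0.0577) and photoreceptor markers (0.0917) changed without KO 3 d replicate 1. Odorant binding proteins (0.191) changed without KO 3 d replicate 3. Photoreceptor markers (0.0913) changed without WT 25 d replicate 2. Odorant binding proteins (0.102) changed without WT 25 d replicate 3. Odorant binding proteins (0.0841) changed without WT 3 d replicate 1. Cuticle proteins (0.158), male markers (0.0772), oxidative defence (0.113) and photoreceptor markers (0.113) changed without WT 3 d replicate 3.

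For age averaged over genotypes, the lists called were cilium genes, cuticle proteins, ribosomal proteins, glia markers, hemocyte markers, muscle markers, odorant receptors, oxidative phosphorylation and photoreceptor markers. For age averaged over genotypes, adjusted p with an estimated correlation was 0.860, 0.644, 0.860, 0.644, 0.770, 0.644, 0.860, 0.860 and 0.644, in that order. By fry, age averaged over genotypes gave 0.600, 0.183, 0.751, 0.183, 0.303, 0.183, 0.827, 0.579 and 0.183, in that order. Age averaged over genotypes without the 3 libraries gave 0.965 for cilium genes, 0.118 for cuticle proteins, 0.350 for hemocyte markers and 0.793 (opposite direction) for odorant receptors. Single omissions for age averaged over genotypes gave a lowest adjusted p of 4.82e-05 for cilium genes, 1.93e-05 for cuticle proteins, 1.39e-19 for ribosomal proteins, 0.000115 for glia markers, 1.92e-05 for hemocyte markers, 0.000149 for odorant receptors, 3.17e-31 for oxidative phosphorylation and 7.18e-15 for photoreceptor markers. Ribosomal proteins (0.0222, opposite direction), glia markers (0.0920) and hemocyte markers (0.100) changed without KO 25 d replicate 1. Cilium genes (0.0738), cuticle proteins (0.133), odorant receptors (0.504), oxidative phosphorylation (0.0913, opposite direction) and photoreceptor markers (0.0572) changed without KO 25 d replicate 2. Odorant receptors (0.295) changed without KO 3 d replicate 3. Odorant receptors (0.0813) changed without WT 25 d replicate 3. Cilium genes (0.368) and odorant receptors (0.932) changed without WT 3 d replicate 3.

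The agreement of age changes between genotypes (r = 0.192) was 0.355 among genes with a mean of at least 5 CPM, 0.117 with the replicate block and 0.0107 without the 3 libraries, and over single omissions it ran from -0.0356 without WT 3 d replicate 3 to 0.254 without KO 25 d replicate 1. That of KO changes between ages (r = 0.401) was 0.650 among genes with a mean of at least 5 CPM, 0.262 without KO 25 d replicate 2 and 0.405 without WT 3 d replicate 1. The exact p for genes within 2 Mb of mir-284 ran from 0.00263 to 0.0319 for KO at 3 d, below 0.05 without any single library of that age, from 7.47e-05 to 0.207 for KO at 25 d, and from 0.000160 to 0.283 for KO averaged over ages. Within 5 Mb it was 0.413, 0.00302 and 0.0155.

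Genes named whatever their values turned in comparisons in which they were not called. In log2, quality weights turned w (-0.00879), GluRIIB (0.0202) and Orco (-0.116) for age in WT and Orco (-0.00309) for KO at 3 d, and limma voom turned Orco (-0.100) for the difference of age changes. Without 2 libraries Orco turned for age in WT (-0.149), age in KO (-0.0616), KO at 3 d (-0.216), KO at 25 d (-0.128), KO averaged (-0.172) and age averaged (-0.105), and GluRIIA for age in KO (0.121). Without 3 libraries it was Orco for age in WT (-0.156), age in KO (-0.252), KO at 3 d (-0.0211), KO at 25 d (-0.117), the difference (-0.0962), KO averaged (-0.0692) and age averaged (-0.204), and GluRIIA for age in KO (0.195). The roX2 covariate turned Orco for KO at 3 d (-0.203), KO at 25 d (-0.0565) and KO averaged (-0.130), GluRIIB for KO averaged (-0.0317), and Ir31a, which was called, for KO averaged (0.0685). Single omissions gave w -0.237 (WT 25 d replicate 3) to 1.17 and Orco -0.155 (WT 3 d replicate 3) to 0.509 for age in WT. For age in KO they gave GluRIIA -0.222 to 0.123 (KO 25 d replicate 1) and Orco -0.0602 (KO 25 d replicate 1) to 0.750. Orco ran from -0.206 (WT 3 d replicate 3) to 0.458 for KO at 3 d, from -0.127 (KO 25 d replicate 1) to 0.700 for KO at 25 d and from -0.312 (KO 25 d replicate 1) to 0.555 for the difference.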

Other observations

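The fit behind the next values, without KO 25 d replicate 1, WT 3 d replicate 3 and KO 3 d replicate 3, the test of a lower share of males and the roX2 covariate were chosen only after the result was seen; KO 25 d then held 1 library. In that fit transcripts of oxidative phosphorylation were lower at 25 d than at 3 d in both genotypes. In WT 40 of 78 members fell and 0 rose (median log2 -0.40, adjusted p = 1.31e-19, and adjusted p = 0.538 with an estimated correlation), among them ATPsyn-gamma (-0.84), blw (-0.73) and sun (-0.71), subunits of the ATP synthase. In KO 11 of 78 fell, with 72 negative (adjusted p = 5.49e-23, and adjusted p = 0.413 with an estimated correlation), among them CoVIb (-0.61) and cype (-0.59), subunits of cytochrome c oxidase. With all 11 libraries the KO list went the other way without passing (median 0.17, 53 of 79 positive, adjusted p = 0.362), and the WT list was lower (median -0.36, adjusted p = 3.48e-11, and adjusted p = 0.748 with an estimated correlation). Without the 3 libraries the muscle markers were lower too. In WT 11 of 20 members fell (median -1.15, adjusted p = 6.87e-29, and adjusted p = 0.312 with an estimated correlation), and in KO 2 fell (median -0.57, adjusted p = 2.06e-10, and adjusted p = 0.413 with an estimated correlation). Photoreceptor markers were lower in KO (median -3.30), and fat body and female markers higher in WT (median 2.89). With all 11 libraries fat body and female markers did not pass in WT (median 0.01, 7 of 14 positive). With all 11 libraries edgeR called 0 oxidative phosphorylation members at either genotype, DESeq2 4 in WT and 1 in KO, and limma voom 0, with 13 and 4 at an unadjusted p under 0.05. Without the 3 libraries voltage-gated channels fell in WT for 8 of 26 members (adjusted p = 0.00157, and adjusted p = 0.578 with an estimated correlation), with Ih at -0.54, para at -0.49 and Sh at -0.42. In KO 18 of 26 members were positive (median 0.18, adjusted p = 0.0493, and adjusted p = 0.5295 with an estimated correlation). The difference of the age changes, KO minus WT, was positive for 21 of 26 (median 0.35, adjusted p = 2.24e-06, and adjusted p = 0.5303 with an estimated correlation), with Sh called (0.76, SE 0.13, adjusted p = 0.0305). Neuron markers (8 of 10 positive, median 0.23, adjusted p = 0.01695), synaptic vesicle genes (20 of 28, 0.23, adjusted p = 0.00358), muscle markers (17 of 20, 0.38, adjusted p = 0.00132) and Johnston's organ markers (10 of 12, 0.40, adjusted p = 0.0254) shifted the same way, each with adjusted p = 0.6209 with an estimated correlation. With all 11 libraries neuron markers and synaptic vesicle genes did not pass (adjusted p = 0.483 and 0.973). There the channel list passed for age neither in WT (adjusted p = 0.186) nor in KO (0.231), and it passed for the difference (adjusted p = 0.0198, and adjusted p = 0.734 with an estimated correlation). The odorant binding protein gene Obp44a rose by 1.93 with age in WT and fell by 1.52 in KO at 3 d without the 3 libraries, and with all 11 libraries Obp44a passed neither test (1.26 and -1.22, adjusted p = 0.595 and 0.465).

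Chaperone transcripts depended on the libraries kept. Hsp83 was at 137 and 127 CPM in WT 3 d replicates 1 and 2 but at 874 CPM in WT 3 d replicate 3, and at 246 and 298 CPM in KO 3 d replicates 1 and 2 but at 1166 CPM in replicate 3, against 887 to 1212 CPM at WT 25 d. DnaJ-1 was at 81.0, 81.6 and 337 CPM in WT 3 d. With all 11 libraries the age change of Hsp83 in WT did not pass (1.41, adjusted p = 0.740). With those libraries left out Hsp83 rose with age in WT by 2.93 (SE 0.16, adjusted p = 3.10e-05) and DnaJ-1 by 1.31, and this omission removed the very libraries in which both were high at 3 d.

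KO 25 d replicate 1 stood apart, and a loss of long transcripts is a candidate explanation. Its log2 ratio to KO 25 d replicate 2 was lower in the longest genes than in the shortest, of 9642 genes split in 3 by length, by a difference of -1.19 (95% bootstrap interval -1.24 to -1.13). The same difference ran from -0.394 to 0.223 for the other libraries against their groups. The 50 most abundant genes held 32.5% of its counts, against 15.8% to 21.8% elsewhere. Without them its median correlation was 0.894, against 0.938 to 0.963, but this weighs genes alike. No biological explanation was tested, and a few abundant genes or a wrong match to its column stay open.

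For KO averaged over ages, other splits of genotype within age argued against chance for the count as a whole. Of 100 splits, 1 gave as many, the real one with 631 genes, and the highest other gave 2. The other splits mix WT and KO libraries within a group, which raises the spread there. They therefore do not tell how many of the 631 calls are due to chance. Sequence linked to the targeted allele was argued against as the whole cause, since 11.9% of the called genes (75 of 631, exact 95% interval 9.46 to 14.7) lay within 5 Mb of mir-284, against 9.11% of all tested genes. A lower share of males in KO could lower male transcripts. Of 286 called lower genes, 40.2% (exact 95% interval 34.5 to 46.1) fell over 1 SE beyond roX1 (-0.98) and roX2 (-1.26). Called genes are selected for large falls, so this share cannot decide. With the roX2 level as a covariate 12 of the 631 calls remained: the median log2 fold change went from -1.28 to -1.08 for the lower genes and from 1.08 to 0.66 for the higher ones, 284 of 286 and 337 of 345 kept their sign, and the median SE went from 0.21 to 0.40 and from 0.19 to 0.39, so folds shrank and precision was lost. Strain background, the loss of mir-284 itself and a difference in sex stay open.

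For age averaged over genotypes, 1 of 100 splits reached the real 51 genes and the highest other gave 3. The others mix ages within a group, with the limit given for KO. For age in WT and KO at 3 d, 10 splits are too few for a share under 0.05: 1 of 10, the real one, gave 18 and 165 genes and the others 0.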
